A study of Homo sapiens with 6 samples.

How the data were processed

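RNA was taken from 6 HepG2 cultures in 2 groups of 3, control guide and EDEM3 knockout, and the labels describe the knockout numbers as separate clones. Total RNA was extracted with RNeasy columns and made into stranded libraries after removal of ribosomal and globin RNA, per the labels' protocols. Reads went through bcl2fastq 1.8.4, Trimmomatic 0.35, FastQC 0.10.1, STAR 2.4.2, Cufflinks 2.2.1 and Cuffdiff, with genome build hg19, per the submitters' processing notes; the version of Cuffdiff and the gene annotation are not given in the sources used here.

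The deposited FPKM values, fragments scaled by transcript length and library size, are the authors' single estimate per gene and genotype over the 3 libraries of each group. The authors' log2 ratios are control over knockout, which was checked against the FPKM values (largest difference 1.08e-05), and they are given here as knockout against control. The p-value and q-value of each gene, and the score that goes with them, are the authors' Cuffdiff results per the file headers. The lowest p-value in the deposited table is 5e-05 (844 genes) and the largest q-value is 0.0499, so the table holds called genes and no others. Upper confidence bounds in the deposited tables lie 2 deposited half-widths from the FPKM value. Lower bounds of some genes with low values, such as DEFB1 in the knockout, are listed at 0 and lie closer. The FPKM of 9 genes differed between the 2 deposited tables by more than 0.001 of its value, and the table of comparisons was used. Positions are those of the hg19 files, whose starts were read as counted from 0 and raised by 1: of 1672 symbols with a RefSeq length, end minus start equalled it for 78 and end minus start plus 1 for 29. Such a position can span overlapping genes, and most spans matched neither.

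The design written before the data were examined expected FPKM per library and planned limma with camera on log2 values with 1 FPKM added. The files do not hold such values, so the authors' calls were used as they stand, with no filter on low values, and Fisher's exact test (2-sided), planned as a second form, replaced camera. It sets called genes of a list that rose or fell against all other called genes. Since every gene tested was selected as changed in these libraries, it asks only about direction, genes are not independent replicates, and the called lists are not evidence independent of the selection. A permutation test was added after the data were examined: 10000 random lists were drawn with the same number of genes in each of 10 bins of mean FPKM. The p-values of each form were adjusted by Benjamini and Hochberg over the 22 lists tested. Of 36 lists fixed beforehand (1241 gene names, 262 among the called genes), 10 had under 5 called genes and 4 none, and these were not tested. A count adjusted over the list alone cannot be given, since list members that were not called have no p-value in the tables used. The cultures' replicate spread is known only through the authors' bounds, and nothing beyond the labels says how far the 3 libraries of a group were separate cultures.

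Both list tests were tested on simulated data: in each of 50 simulated tables the directions of the 1829 genes were drawn from the share of rises in their abundance bin, and a list of 20 genes was planted with 95% rises. Both forms recovered the planted list in 50 of 50 tables. Among lists with nothing planted, Fisher's exact test called 33 of 1100 (3.0%) and the permutation 1 of 1100 (0.0909%). Planted falls and shorter planted lists were not simulated, so the recovery of such lists is unknown. The planted genes were drawn from called genes of any abundance, many of them low, where rises are rare and planted rises stand out. Lists of abundant genes, such as the cell cycle list, were not planted. Their recovery, above all by the permutation, may be lower. Directions were drawn gene by gene, so the shares of false calls leave out any agreement between neighbouring genes.

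Genes were named by a rule set before the data were examined: EDEM3 and LRP1, the 12 largest rises and 12 largest falls on the log2 scale with 1 FPKM added among genes of at least 1 FPKM in the higher group, leaving out unnamed loci and non-coding transcripts, and up to 4 genes of each list with the lowest q-value. The rule asked for libraries that do not overlap between groups; the authors' bounds took their place (722 genes had bounds apart), and ties of q-value were ordered by the authors' test score, genes listed at 0 first. List members outside the rule (ACSL3, C5, C8A, APOM and LIPG, the exceptions to the direction of their lists) were named after their values were seen. A gene that maps to the Y chromosome is not named, and some genes that the rule selects are not reported here. Depth per library is unknown, exact binomial intervals (95%) cover counting error only, and counting by strand is not stated, so overlapping genes remain uncertain. Alternatives covered low-value filters of 0.5 and 2 FPKM, a 2-fold limit, pseudocounts of 1, 0.1 and 0.01 FPKM, 2 scalings, a q-value limit of 0.01 and the removal of genes or chromosomes. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.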

Results

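Messenger RNA was measured by sequencing in HepG2, a human hepatoma line that keeps many functions of hepatocytes. The 6 libraries were 3 from cells given CRISPR-Cas9 with a control guide and 3 from cells made deficient in EDEM3, an enzyme of the endoplasmic reticulum that trims mannose from misfolded glycoproteins and so marks them for degradation. The title of the series ties EDEM3 to plasma triglyceride through LRP1, a receptor that clears lipoprotein remnants, and the comparison asks which transcripts differ when EDEM3 is lost. The tables used here hold 1 FPKM value per gene and genotype, with the authors' confidence bounds, for 1829 genes that the authors called different. No value per library was used, so the bounds are the only measure of spread, and the sequencing depth is unknown.

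EDEM3 itself fell to 12.8% of the control level in the knockout, from 10.4 FPKM (bounds 8.17 to 12.7) to 1.33 FPKM (bounds 0.877 to 1.78). The genes that fell furthest included SPINK1, a secreted trypsin inhibitor, from 432 to 2.65 FPKM, carbonic anhydrase CA2 from 17.7 to 0.292 FPKM. The acid phosphatase ACP5 fell from 7.10 to 0.0587 FPKM and the mitochondrial outer membrane protein TSPO from 11.2 to 0.314 FPKM. The intermediate filament gene VIM had 17.3 FPKM in the control and was listed at 0 in the knockout. Genes that rose most included the actin-binding protein gene TAGLN, from 16.8 to 77.5 FPKM, the metallothionein MT1M from 1.06 to 7.75 FPKM. The skeletal actin ACTA1 rose from 3.87 to 15.3 FPKM and the imprinted gene DLK1 from 26.0 to 87.4 FPKM. Of the 1829 genes in the authors' deposited table, 1276 (69.8%) were lower in the knockout and 553 (30.2%) were higher.

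The other large falls were DEFB1, an antimicrobial peptide, from 13.1 to 0.458 FPKM, CHI3L1 from 11.2 to 0.289 FPKM. IGFBP2, which binds insulin-like growth factors, fell from 14.4 to 1.24 FPKM, C2orf82 from 48.9 to 6.79 FPKM and the mitochondrial carrier SLC25A47 from 23.3 to 2.82 FPKM. The histone gene HIST3H2BB (46.0 FPKM in the control) and C19orf63 (5.11 FPKM) were listed at 0 in the knockout. The other large rises were the cytokine IL18 from 2.70 to 11.04 FPKM, FAM19A4 from 8.19 to 22.4 FPKM, and ASRGL1 from 11.99 to 30.8 FPKM. The activin antagonist FST rose from 61.9 to 146 FPKM, UGT2B11 from 6.96 to 17.3 FPKM and MGC12916 from 17.2 to 40.9 FPKM. A further 2 metallothioneins, MT1G and MT1F, are given with their group. Bounds that did not overlap between the groups were a condition for naming these genes.

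EDEM3 lies on chromosome 1 from 184659625 to 184724041 in hg19, the build of the files, and its q was 0.000784 in the authors' deposited table, the lowest the table holds. LRP1 has no row in the tables used and was not analysed here. Rises were mostly small and falls were larger: the median rise was 1.39-fold and the median fall 2.201-fold, with the genes listed at 0 ranked as the largest falls. The genes that rose were also more abundant, with a median mean of 20.3 FPKM against 2.38 FPKM for those that fell. The sizes of rises and falls were not compared at like abundance. A change of at least 2-fold was seen in 52 of the 553 genes that rose and in 710 of the 1276 that fell. The knockout was listed at 0 for 105 genes and the control for none. Genes that many cell types use, such as INSIG1, were among them, so these genes are reported only as listed at 0. All these genes were selected on the same libraries that give their values, so the sizes of change near the threshold are biased upward.

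**Figure D1:**
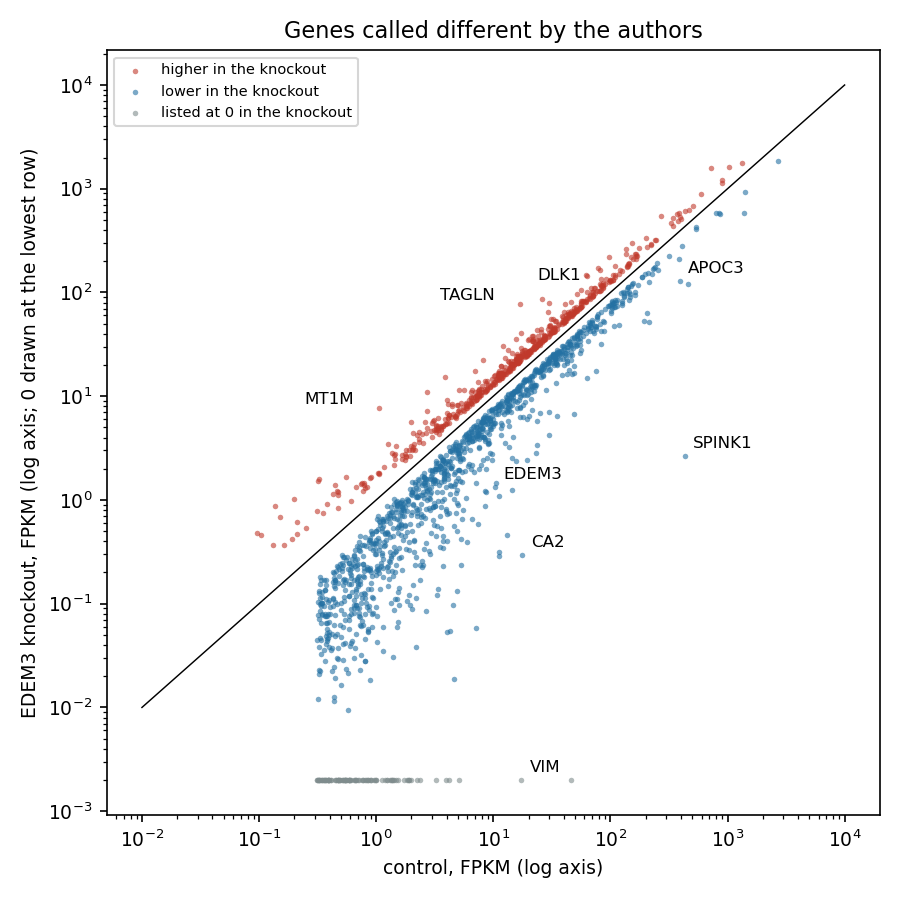
Each point is a gene called different by the authors, with its FPKM in the control on the horizontal axis and in the EDEM3 knockout on the vertical axis, both logarithmic; genes listed at 0 are drawn at the lowest row and the line marks equal values. Most genes above the line lie close to it, with exceptions such as TAGLN and MT1M (52 of all 553 rises were at least 2-fold). Many of the genes below it, SPINK1 and CA2 among them, lie far from it.

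Of the 37 genes fixed for triglyceride-rich lipoproteins 15 were called, of which 13 fell and 2 rose. APOA5, which activates lipoprotein lipase, fell from 63.2 (bounds 50.2 to 76.2) to 15.1 FPKM (11.5 to 18.8). APOC3, an inhibitor of lipoprotein clearance, fell from 393 (bounds 313 to 473) to 129 FPKM (101 to 157). MTTP, which loads lipid onto apolipoprotein B, fell from 38.9 (bounds 31.0 to 46.9) to 16.1 FPKM (12.6 to 19.6). C19orf80, also known as ANGPTL8, fell from 82.9 to 31.9 FPKM. The 2 that rose were APOM, from 154 to 299.6 FPKM, and the endothelial lipase LIPG, from 4.04 to 6.95 FPKM. Against the other called genes the list had an adjusted p of 0.411 by Fisher's exact test and 0.0577 by permutation within abundance bins. Some of the falls come from genes that lie close together, such as APOA5 and APOC3 on chromosome 11. Both tests count each of these as a separate gene. Over 10 alternatives the permutation gave from 0.0187 (equal medians) to 1 (a 2-fold limit) and was under 0.05 in 4, so whether this list leaned further down depends on the setting.

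Of 46 fixed genes of fatty acid and triglyceride synthesis 12 were called and 11 of these fell: the desaturase FADS2 from 23.8 to 5.74 FPKM, the acyltransferase AGPAT2 from 21.4 to 7.33 FPKM, among others. The lipid droplet coat protein PLIN2 fell from 162 to 94.8 FPKM and the fatty acid carrier FABP1 from 212 to 126 FPKM. ACSL3 rose. Of 42 fixed genes of fatty acid oxidation and ketogenesis 10 were called and all of these fell. The electron carrier ETFB fell from 387 to 212 FPKM and CYP4F2 from 5.24 to 2.37 FPKM. The adjusted p was 0.267 and 0.139 by Fisher's exact test, and 0.0459 and 0.0165 by permutation within abundance bins. The permutation called these lists in 5 of 8 and 6 of 8 alternatives that could test them. Without chromosomes 6, 14 and 17 the counts were 11 of 12 and 9 of 9 lower, with a permutation adjusted p of 0.169 and 0.111. Of cholesterol synthesis, DHCR7 fell from 107.5 to 78.7 FPKM and TM7SF2 from 115 to 84.0 FPKM, and EBP rose from 99.3 to 132 FPKM. INSIG1, a regulator of the pathway, was listed at 0 in the knockout against 2.23 FPKM.

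Of 49 fixed genes of complement and coagulation 24 were called and 22 of these fell. The fibrinogen chain FGB fell from 203 (bounds 160.1 to 247) to 63.0 FPKM (48.1 to 77.8), and the fibrinolysis inhibitor CPB2 from 55.4 to 26.3 FPKM. The terminal complement components C6 and C7 fell from 2.498 to 0.695 and from 0.716 to 0.0815 FPKM. C5 and C8A rose. The adjusted p was 0.0995 by Fisher's exact test and 0.00440 by permutation within abundance bins. Both tests count neighbours separately, such as the fibrinogen chain genes on chromosome 4 and C6 and C7 on chromosome 5. Without chromosomes 6, 14 and 17, 19 of 21 fell and the permutation gave 0.104; it called the list in 6 of 9 alternatives. All 3 called genes of bile acid synthesis fell: CYP7A1, its rate-limiting enzyme, from 5.40 to 0.656 FPKM, the conjugating enzyme BAAT from 2.42 to 0.726 FPKM and HSD3B7 from 44.9 to 32.1 FPKM. Cytochrome P450 and drug metabolism genes fell in 15 of 19 cases (adjusted p = 0.596, Fisher's exact test; adjusted p = 0.145, permutation within abundance bins). Each test called this list in 1 of 10 alternatives. CYP3A5 fell from 23.5 to 3.38 FPKM, CYP3A7 from 12.7 to 3.52 FPKM, FMO5 from 29.9 to 4.23 FPKM and SLCO2B1 from 13.7 to 3.26 FPKM.

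**Figure D2:**
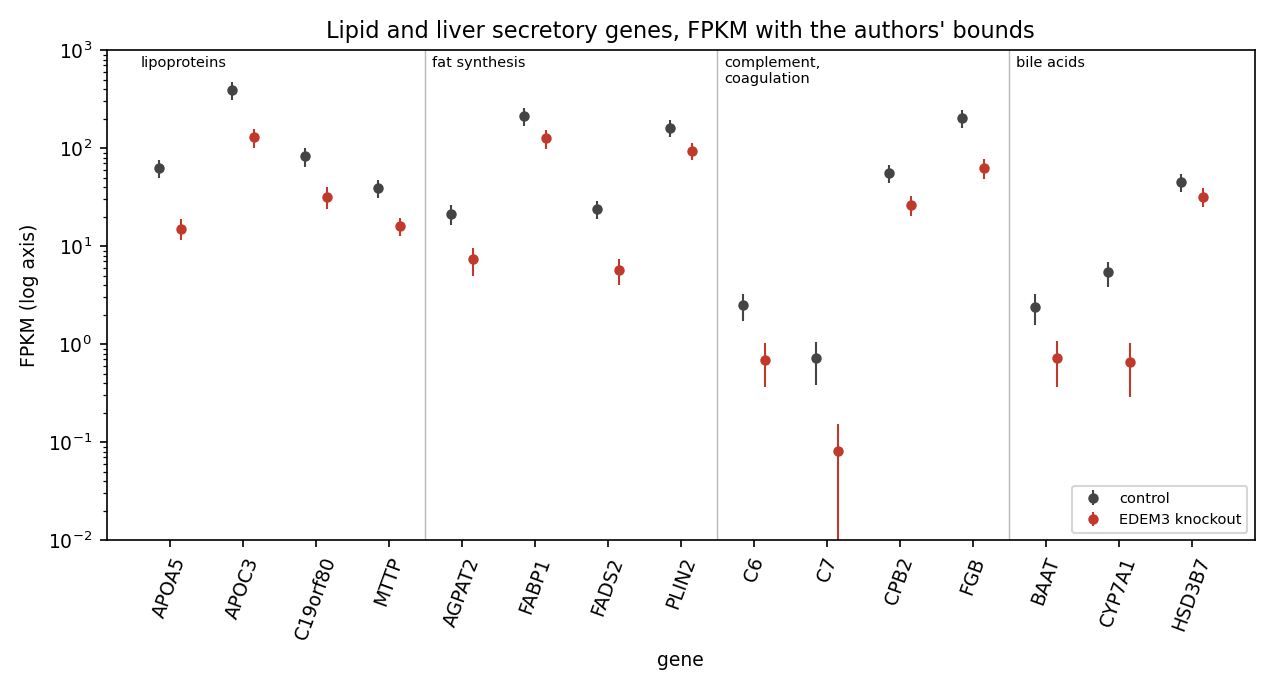
FPKM on a logarithmic axis in the control (grey) and the EDEM3 knockout (red) for up to 4 genes each of the lipoprotein, fat synthesis, complement and coagulation, and bile acid lists, with bars for the authors' confidence bounds; bounds under 0.01 FPKM are drawn to the axis. APOA5 fell from 63.2 to 15.1 FPKM, and all genes shown were lower in the knockout. The called members of these lists that rose (APOM, LIPG, ACSL3, C5 and C8A) are not among the genes shown.

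Hepatocyte markers were split, 7 lower and 6 higher (adjusted p = 0.411, Fisher's exact test). ADH1B fell from 3.33 to 0.122 FPKM, the gluconeogenic enzyme PCK1 from 3.50 to 0.693 FPKM and the urea cycle enzyme OTC from 2.02 to 0.0894 FPKM. A1BG rose from 13.4 to 27.6 FPKM. Acute phase genes were lower in 5 of 8 cases, with SERPINA3 going from 457 to 120 FPKM and ITIH4 from 2.21 to 0.284 FPKM. The interleukin antagonist IL1RN rose from 21.5 to 33.9 FPKM and ceruloplasmin (CP) from 17.01 to 24.3 FPKM. Fetal liver and progenitor markers were higher in 5 of 8 cases, among them DLK1 and PEG10 (137 to 235 FPKM). SOX4 fell from 12.8 to 8.97 FPKM. For the acute phase and fetal lists the adjusted p was 0.738 and 0.176 by Fisher's exact test.

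Chaperones of the unfolded protein response rose in 6 of 7 called genes. HSPA5 (BiP), the main chaperone of the endoplasmic reticulum, rose from 120 (bounds 95.1 to 146) to 165 FPKM (129.96 to 200.4), CRELD2 from 23.2 to 31.5 FPKM and HYOU1 from 43.7 to 57.1 FPKM. The hepatic transcription factor CREB3L3 fell from 4.76 to 1.17 FPKM. The adjusted p was 0.0243 by Fisher's exact test, which called the list in 3 of 7 alternatives, and 0.219 by permutation within abundance bins. The 3 called targets of ATF4 and CHOP were lower: NUPR1 from 46.5 to 26.9 FPKM, DDIT4 from 45.0 to 33.1 FPKM and STC2 from 18.5 to 14.5 FPKM. Of the 46 genes of endoplasmic reticulum-associated degradation 2 were called. NPLOC4 rose from 45.5 to 60.1 FPKM and UBXN6 fell from 32.0 to 24.4 FPKM. In the LDL receptor family and lipoprotein uptake 4 of 32 were called. Among them LRP8 rose from 2.74 to 4.89 FPKM. LRP4 fell from 2.06 to 0.912 FPKM and LRP11 from 34.1 to 25.5 FPKM. In lysosome and autophagy genes 8 of 9 were lower (adjusted p = 0.411, Fisher's exact test). The protease CTSB fell from 226 to 151 FPKM, CTSZ from 0.827 to 0.0923 FPKM and LAMP2 from 66.4 to 49.0 FPKM, and WIPI1 rose from 27.0 to 38.0 FPKM.

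Of 58 fixed cell cycle and DNA replication genes 15 were called and 14 of these rose. The replication factor CDC6 rose from 34.6 (bounds 27.4 to 41.8) to 52.7 FPKM (41.9 to 63.5), the helicase subunit MCM3 from 82.5 to 117 FPKM and the transcription factor E2F1 from 25.01 to 34.7 FPKM. UBE2C, of the mitotic ubiquitin pathway, fell from 72.2 to 40.8 FPKM. Both tests called this list (adjusted p = 1.13e-05, Fisher's exact test; adjusted p = 0.0165, permutation within abundance bins). Fisher's exact test did so in 8 of 8 alternatives that could test it, and the permutation lost it with equal medians (adjusted p = 0.0717) and at q under 0.01 (adjusted p = 0.29997). Of the 11 genes that lie outside chromosomes 6, 14 and 17, 10 rose. All 6 called zinc finger genes of the chromosome 19 KRAB clusters, a family that includes many transcriptional repressors, rose as well (adjusted p = 0.00825, Fisher's exact test, and adjusted p = 0.00660, permutation within abundance bins). Quantile normalization ended both calls (adjusted p = 0.0765, Fisher's exact test; 0.0704, permutation). At a mean of at least 2 FPKM Fisher's exact test gave 0.0688 for 5 genes, and at q under 0.01 only 2 were left. ZNF257 rose from 0.138 to 0.866 FPKM, ZNF788 from 2.09 to 3.46 FPKM, ZNF799 from 5.12 to 7.40 FPKM and ZNF114 from 7.17 to 9.98 FPKM.

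Metal-binding genes rose in 7 of 9 cases. Among the metallothioneins MT1E rose from 269 to 546 FPKM, MT1X from 135 to 261 FPKM, MT1G from 96.8 to 221 FPKM and MT1F from 63.6 to 145 FPKM. These near-identical copies can share reads, so the value of each is uncertain. They also lie close together on chromosome 16, and both tests count each of them as a separate gene. The adjusted p was 0.0243 by Fisher's exact test, which called the list in 4 of 8 alternatives, and 0.298 by permutation within abundance bins. NRF2 targets rose in 4 of 6 cases, including GSR from 118 to 150.2 FPKM and GCLC from 25.04 to 32.7 FPKM (adjusted p = 0.176, Fisher's exact test). HMOX1 fell from 66.7 to 50.9 FPKM. Hypoxia and glycolysis genes were lower in 12 of 14 cases (adjusted p = 0.411, Fisher's exact test; adjusted p = 0.252, permutation within abundance bins). Fisher's exact test called this list in 1 of 9 alternatives and the permutation in none. NDRG1 fell from 34.8 to 6.47 FPKM, CA9 from 4.93 to 0.505 FPKM, ALDOC from 8.48 to 1.23 FPKM and HK1 from 1.82 to 0.488 FPKM. WNT targets were lower in 9 of 10 cases (adjusted p = 0.411, Fisher's exact test; adjusted p = 0.0459, permutation within abundance bins, and 0.387 without chromosomes 6, 14 and 17, where 7 of 8 fell). The permutation called this list in 4 of 8 alternatives. BAMBI fell from 44.1 to 17.8 FPKM, TNFRSF19 from 64.3 to 34.3 FPKM and SLC1A2 from 20.5 to 13.8 FPKM. The WNT inhibitor DKK1 rose from 82.0 to 164 FPKM.

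**Figure D3:**
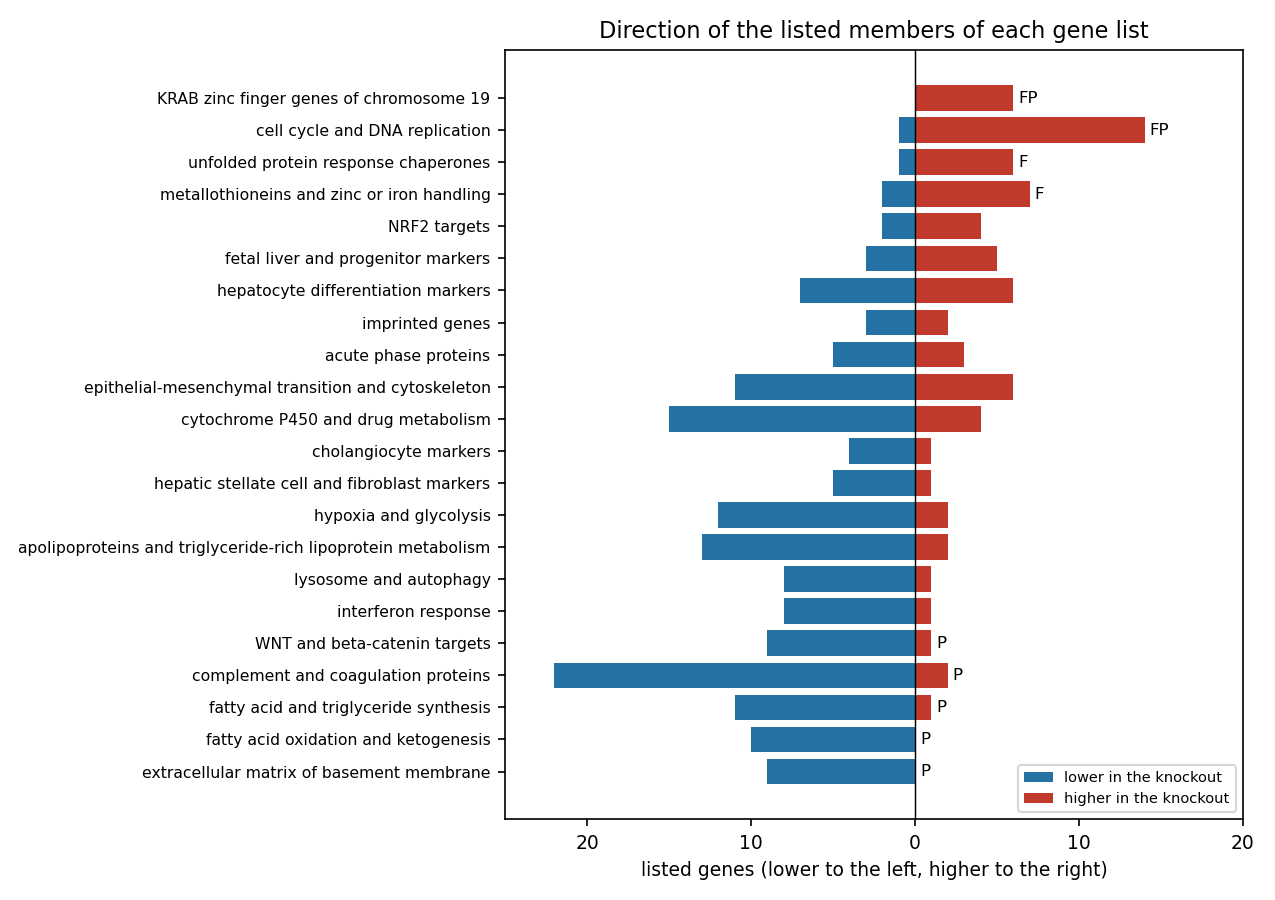
Bars give the number of called genes that were lower (blue, left) or higher (red, right) in the EDEM3 knockout for each of the 22 lists tested; F marks an adjusted p under 0.05 by Fisher's exact test and P by permutation within abundance bins. Both letters stand beside cell cycle genes (14 of 15 higher) and KRAB zinc finger genes (6 of 6 higher).

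Basement membrane genes were lower in all 9 cases (adjusted p = 0.176, Fisher's exact test; adjusted p = 0.0459, permutation within abundance bins, and 0.160 without chromosomes 6, 14 and 17, where all 9 remained). The permutation called this list in 5 of 8 alternatives. The collagen COL4A2 fell from 1.53 to 0.0659 FPKM, the laminins LAMA3 from 4.12 to 1.72 FPKM and LAMB3 from 1.68 to 0.414 FPKM, and TINAGL1 from 26.7 to 15.5 FPKM. Genes of epithelial-mesenchymal transition and the cytoskeleton were split, 11 lower and 6 higher. ITGA5 fell from 1.34 to 0.288 FPKM and ANKRD1 rose from 56.3 to 105 FPKM. MSN (0.893 FPKM) and TWIST1 (0.542 FPKM) were listed at 0 in the knockout. Markers of stellate cells and fibroblasts were lower in 5 of 6 cases, COL6A1 going from 3.08 to 0.646 FPKM and COL6A2 from 1.13 to 0.0347 FPKM beside VIM, against the rise of TAGLN. Cholangiocyte markers were lower in 4 of 5 cases, SPP1 from 1376 to 589.6 FPKM and TFF3 from 11.6 to 4.24 FPKM. ONECUT2 rose from 1.45 to 2.48 FPKM. None of the last 3 lists stood apart from the other called genes (adjusted p = 0.738, 0.738 and 1, Fisher's exact test).

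Of markers of further cell types, the endothelial genes ENG and EGFL7 fell (0.933 to 0.113 and 2.96 to 1.20 FPKM) and ESAM rose (5.83 to 8.67 FPKM). Of macrophage and leukocyte markers LYZ rose from 722 to 1583 FPKM and CD74 fell from 17.3 to 10.2 FPKM. Interferon response genes were lower in 8 of 9 cases (adjusted p = 0.411, Fisher's exact test). IFITM2 fell from 48.9 to 19.8 FPKM, IFITM3 from 83.4 to 42.5 FPKM, BST2 from 101 to 62.8 FPKM and PARP14 from 15.9 to 11.2 FPKM. Imprinted genes were split, with ZDBF2 falling from 1.44 to 0.112 FPKM and SNURF from 104 to 70.3 FPKM against the rises of DLK1 and PEG10 (adjusted p = 0.738, Fisher's exact test). NFKBIA and NFKB1 rose (156 to 208 and 19.7 to 25.8 FPKM) and TNFAIP2 fell (1.64 to 0.796 FPKM). The cancer-testis genes TEX15 and PRAME fell (1.19 to 0.480 and 0.746 to 0.0612 FPKM). Of histone genes, HIST1H1D fell from 19.2 to 2.41 FPKM and HIST1H2AE rose from 389 to 538 FPKM. No ribosomal protein, p53 target, mitochondrially encoded gene or nuclear gene of oxidative phosphorylation from the fixed lists was among the called genes.

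Direction went with abundance. Of called genes with a mean under 1 FPKM 95.1% were lower in the knockout (446 of 469), and of those with a mean of at least 20 FPKM 46.0% were (239 of 520). Fisher's exact test, planned as a second form, does not take this into account, and the permutation within abundance bins was added after the data were examined. Of the 22 lists the first called 4, the second 7 and both 2. Quantile normalization of the 2 columns turned the split to 891 lower and 938 higher, and scaling to equal medians left 1192 lower and 637 higher. Over all alternatives the majority direction of a tested list turned in 3 cases: acute phase genes with equal medians (5 of 8 higher), imprinted genes with quantile normalization (3 of 5 higher) and cytoskeleton genes at a mean of at least 2 FPKM (5 of 9 higher). It became even in 4 cases, 3 of them acute phase genes and 1 hepatocyte markers.

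By chromosome, the share of called genes that rose was highest on chromosomes 14 (69 of 108), 6 (77 of 132) and 17 (71 of 126), against 22.97% on all others together (336 of 1463). On chromosome 14, 58 of the 69 rises lay between 20 and 40 Mb, where 58 of 65 called genes rose (median rise 1.47-fold). On chromosome 6 the part under 60 Mb held 62 rises among 89 called genes (median 1.37-fold), and on chromosome 17 the part from 20 Mb held 69 among 109 (median 1.33-fold). APOM, MCM3 and GCLC lie in that part of chromosome 6, NFKBIA in that of chromosome 14, and CDC6, NPLOC4 and WIPI1 in that of chromosome 17. All 21 called genes of chromosome 21 fell, as did 54 of 61 on chromosome 22. Of the 23 chromosomes tested, chromosomes 6, 14 and 17 held more rises than abundance-matched lists (adjusted p = 0.00153 each, permutation within abundance bins) and 5 held fewer: 11, 19, 21, 22 and X (adjusted p from 0.00230 to 0.0259, permutation). The matched lists drew on all called genes, those of chromosomes 6, 14 and 17 included, which raises the rises expected elsewhere. The 5 were not tested against the other chromosomes alone, so they are not findings separate from the 3. The test by chromosome and the bounds in Mb were chosen after the data were examined.

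**Figure D4:**
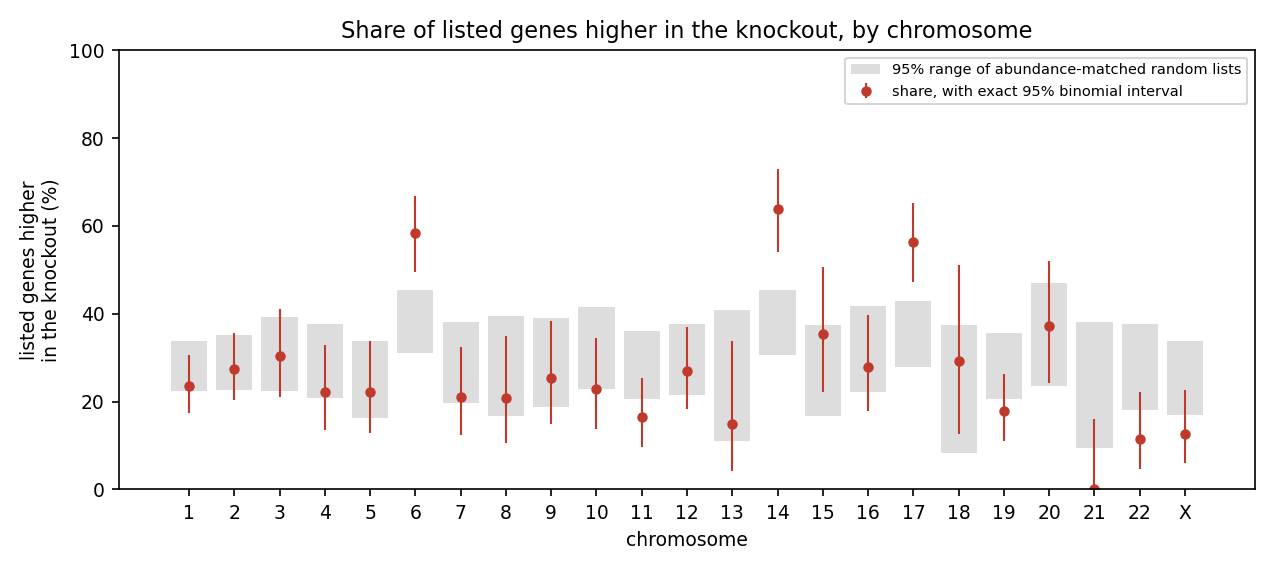
Share of called genes that were higher in the EDEM3 knockout on each chromosome, in percent, as points with exact 95% binomial intervals; grey bars give the 95% range of 10000 random lists matched on abundance. Chromosomes 6, 14 and 17, at 58.3%, 63.9% and 56.3%, lie above their grey bars.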

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

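The alternatives with a q-value under 0.01, without genes at 0, without chromosomes 6, 14 and 17, with the second table's FPKM, and the permutation within abundance bins were chosen after the data were examined; the others were planned. The count of 1829 called genes became 1194 at a mean of at least 2 FPKM, 762 with at least a 2-fold change and 254 with at least a 2-fold change after adding 1 FPKM, since fewer genes can pass, and it stayed within 1.5 times of 1829 under the 4 further settings that could change it, from 1276 at q under 0.01 to 1724 without genes at 0; the second table and the scalings do not redo the authors' calls. The share lower in the knockout (69.8%) was 64.4% at a mean of at least 0.5 FPKM and 57.0% at a mean of at least 2 FPKM. It was 93.2% with a 2-fold change and 91.3% with a 2-fold change after adding 1 FPKM. It was 76.96% at q under 0.01 and 77.03% without chromosomes 6, 14 and 17. It was 65.2% after scaling to equal medians, which removed a median of -0.41 on the log2 scale, knockout against control. It turned to 48.7% under quantile normalization; both scalings run over called genes alone, so they also remove the surplus of falls itself. The lists called by Fisher's exact test numbered 4, became 0 under either 2-fold setting, 2 at q under 0.01, 2 after scaling to equal medians, 8 under quantile normalization and 7 under the permutation within abundance bins, which shared 2 with the 4; the cause was not tested. At a mean of at least 0.5 FPKM 3 lists were called, of which 2 were among the 4, and at a mean of at least 2 FPKM 3, of which 1 was. Chaperones and metallothioneins were lost at both (adjusted p = 0.0514 and 0.0954 for each, Fisher's exact test) and complement and coagulation was gained; KRAB zinc fingers were lost and fatty acid oxidation gained at the higher limit. EDEM3 was -2.97 on the log2 scale, -2.29 with 1 FPKM added, which shrinks low values by construction, -2.56 after scaling to equal medians and -2.16 under quantile normalization. No paired analysis was possible because the tables used hold 1 value per genotype. For the same reason leaving out each replicate, limma with and without a trend, camera in its forms and fry were not run. LRP1 was not analysed here, and pseudocounts do not enter the authors' calls. Depth is unknown, so no limit of detection can be given.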

Other observations

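Genes of the HOX clusters, which set positional identity and are mostly silent in adult liver, were chosen after their values were seen. Of 16 on the authors' list of called genes 15 were lower in the knockout, and 9 of these were listed at 0 there, including HOXB9 (1.72 FPKM in the control), HOXD11 (1.52 FPKM) and HOXB6 (0.966 FPKM). HOXC9 fell from 2.47 to 0.255 FPKM and HOXA10 from 1.90 to 0.122 FPKM, while HOXD1 rose from 4.02 to 9.23 FPKM. The X-linked BEX genes did not move together: BEX4 fell from 4.93 to 0.131 FPKM and BEX2 from 5.05 to 0.893 FPKM, and BEX1 rose from 25.5 to 41.6 FPKM. Falls prevailed among all called genes of this abundance, and neither the falls nor the zeros of the HOX genes were tested against genes of like abundance.

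Of the tests that follow, the share of kidney-line genes and the agreement of neighbouring genes were written before their results were seen, and the rest after.

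Among genes near 0 in the knockout and present in the control, noise near the detection floor would leave bounds that overlap. The bounds lay apart for all 173 genes of at least 1 FPKM in the control that fell at least 4-fold or to 0. For the 27 of them that fell to 0 the knockout bounds are 0 as well. All 173 had already been called from the same estimates and were chosen for large falls. Bounds apart were thus nearly given and cannot decide about noise. Of genes with a mean under 1 FPKM 95.1% were lower in the knockout (exact 95% interval 92.7 to 96.9). There noise stays open because depth is unknown. Failed estimates written as 0 are not the whole of it, since without them 96.7% of changes of at least 4-fold were falls (292 of 302), and for the 105 genes at 0 they stay open. A background of genomic DNA was assumed to add a like FPKM to every gene, which was not measured. In the control 245 called genes had an upper bound under 1 FPKM. This argues against such an even background for the genes at 0 that reach 1 FPKM there (27 of 105), and an uneven background stays open. For the lower genes at 0, 5 genes near the floor had an upper bound under 0.312 FPKM, too few to decide. RNA of another cell type in the control was looked for with 42 genes typical of an embryonic kidney line, written down after the largest falls had been seen (3 are also in a fixed list), of which 11 were called and 9 were lower, the median of abundance-matched lists (range 6 to 11 of 11, so that no outcome could exceed it); the most abundant of them were FSCN1 (50.8 to 30.8 FPKM) and BEX1, which rose, and this source cannot be told apart from the general surplus of falls. Different HepG2 subclones in the 2 groups, or the loss of EDEM3, may account for the pattern, and with 1 value per gene and group the libraries that carry these genes cannot be seen.

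The direction of change differed between chromosomes. Abundance of the genes on these chromosomes does not account for it, since of all 23 tested 8 lay apart from abundance-matched lists after adjustment (permutation), 6, 14 and 17 with more rises and 5 with fewer. Neighbouring called genes had the same direction in 68.4% of 1805 pairs, against 58.7% when directions were permuted within abundance bins (95% range 56.7 to 60.6; p = 0.0001, permutation). Blocks of altered copy number in the clones are a candidate explanation, but neighbours can also be regulated together, no DNA was measured here, and whether 1 or all knockout clones carry such blocks is open. An effect of EDEM3 itself was not tested.

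Hepatic and lipid genes, 8 of the fixed lists joined after their counts were seen, were lower in the knockout in 86 of 104 cases, while cell cycle genes were higher in 14 of 15. Abundance of the listed genes may account for part of it: 3 of the 7 lists large enough to test were lower than abundance-matched lists after adjustment (permutation), and none of the 3 stayed so under every alternative. Without chromosomes 6, 14 and 17, 90.9% of 11 cell cycle genes rose (exact interval 58.7 to 99.8; adjusted p = 0.0133, permutation within abundance bins), so blocks of altered copy number on these 3 alone do not carry the cell cycle rises; blocks elsewhere were not tested for this list. Of the 86 falls of hepatic and lipid genes 78 lie outside chromosomes 6, 14 and 17, as do 1127 of all 1276 falls. These chromosomes were singled out for their rises, so this count cannot decide whether blocks of altered copy number carry the falls. Blocks on other chromosomes were not tested for these falls. The lean of these lists against other called genes is open too. Without these chromosomes 0 of the 3 lists kept their permutation call, while 19 of 21, 11 of 12 and 9 of 9 still fell. The share of rises among all called genes went from 30.2% to 22.97%, inside the interval of the 93 joined genes (16.1%, 9.32 to 25.2). A response to EDEM3 loss and a difference in growth or differentiation between the clones and the control cells both remain open as hypotheses, since the labels name the cells as clones.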
